A study of Homo sapiens with 5 samples.

How the data were processed

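RNA from 5 MCF12A cultures was hybridised to Affymetrix human Gene ST arrays, 1 array per group. The deposited values are intensity on a linear scale, computed with RMA per the submitters' processing notes, whose version is not given in the sources used here. RMA corrects background, quantile-normalises the arrays of a batch and summarises the probes of a set by median polish. The values came in 2 tables that belong to different array designs, one with the 3 arrays of the untreated, ethanol and acetaldehyde cultures and one with the clone and its control. The tables were treated as normalised separately, so differences were taken only within a table. The labels' protocols give one array design for 1-week and another for 4-week exposures, yet the clone is labelled with 4 weeks and sits on another design than the other 4-week arrays, which was not resolved. The 1-week exposures and microRNA measurements mentioned there were not used here. The array design therefore cannot be told apart from the pair of cultures in any level set across tables.

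Log2 of each deposited intensity was taken first. Probes were named through an annotation table of each array design. Among the 3 arrays processed together, 19181 probes had exactly 1 symbol, 2055 had several and 12061 were unlisted, and for the clone and its control the numbers were 19460, 1754 and 12083. Of the probes with 1 symbol, 19143 and 19429 matched a current RefSeq gene record, from a table of names for human assembly GRCh38.p14, and 0 were renamed. No genome build is given in the sources used here, and no coordinates are printed. Probes with several symbols and unlisted probes were not named. A gene with several probes (895 and 769 of 17958 and 18417 genes) was taken from its brightest probe.

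A difference was counted only where the higher of both arrays reached the median of its table, an intensity of 70.2 in the first table and 92.0 in the second. Genes at or past 2-fold were counted. Counts, log2 differences and list medians use the values as deposited. Folds against an array under the floor are given as at least the brighter value over the floor, a rule added after the data were seen. The floor is the median of each table and not a measured background. With 1 array per group there is no estimate of spread between cultures, so no test was run and no p-value is given. Among those 3 arrays, 43.9% of probes had equal log2 values in ethanol and control, within 1e-06, and 48.2% in acetaldehyde and control, against 1.02% for the clone and its control. The standard deviation across genes was 0.50 for ethanol, 0.25 for acetaldehyde and 0.97 for the clone, so counts of the tables are not on one footing.

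Before the data were examined, 32 gene lists with 689 genes were fixed, of which 639 were measured. They cover epithelial and mesenchymal identity, stress, metabolism, signalling, growth and markers of other cell types. For each list with at least 5 genes past the floor, the median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. A list is described as higher or lower where its median lay outside the middle 95% of random lists and was at least 1.5-fold. The requirement of 1.5-fold was added after the data were seen. Counts of list members below are out of those past the floor in that comparison. The genes named were chosen by a rule fixed before the data were examined: the 12 furthest from control each way, the 8 furthest each way for acetaldehyde against ethanol, up to 20 past 2-fold in all 3 control comparisons, and 2 to 4 members of each list by size, with the metallothioneins and alcohol and aldehyde genes by name. Genes named outside that rule, among them CDH1, VIM, KRT18 and the collagen genes, are members of the fixed lists that were chosen after their values were seen.

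The correlation of ethanol and acetaldehyde differences was set beside 100 simulations of unchanged arrays against 1 shared control, with noise taken from the difference of the treated arrays, and overlaps beside the number that independent lists would share. The calculations were tested on simulated data with 200 changed genes per comparison. At a log2 change of 1.5 the share recovered was 98% for ethanol (11472 genes), 95% for acetaldehyde (11444), 96% for the clone (11526) and 95% for acetaldehyde against ethanol (11473). At a log2 change of 3 it was 100% in each. Unchanged genes called numbered 8, 4, 4 and 7, in the same order. The simulated noise was a fixed value, the same in every comparison and not taken from these arrays. These shares therefore check the calculations and do not measure how reliable the calls are here. Alternatives covered the floor, the fold, centring, a lowess correction for brightness, quantile normalisation again, the mean of a gene's probes, all probes, rank correlation and unmatched random lists, and, added after the data were seen, values under the floor raised to it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.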

Results

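Gene expression was measured in MCF12A, an established non-tumorigenic line of human breast epithelial cells grown as a monolayer, on 5 Affymetrix Gene ST arrays of biotin-labelled total RNA. Per the labels, 1 array came from an untreated culture, 1 from cells kept for 4 weeks in 2.5% ethanol and 1 from cells kept for 4 weeks in 1% acetaldehyde, the first oxidation product of ethanol. A further pair came from a clone that had grown in soft agar, a test of growth without anchorage, after ethanol exposure, and from its own control. The labels put the ethanol of the clone at 2.5% in one place and at 2.5 mM in another, so no dose is set beside its values. The soft agar control is labelled as untreated but also carries a soft agar selection tag, and it is called the clone's control here. Each array held 33297 probes. The first 3 arrays had median intensities of 69.98, 70.23 and 70.61, and the clone's control and the clone had medians of 94.0 and 89.9. With 1 array per group, no difference below has a replicate check, no test was possible, and the number of arrays limits the precision. Folds compare single arrays within one table. Where the dimmer array lay under the intensity floor, the fold was taken against the floor and is given as at least that size, while counts and log2 differences use the values as deposited.

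The first comparison asked which genes differ after 4 weeks in ethanol. The ethanol array had far lower levels of the genes that hold epithelial cells together and higher levels of mesenchymal genes. CDH1, which encodes E-cadherin, was 9.49-fold lower, at an intensity of 117 against 1114 in the control. FN1, which encodes the matrix protein fibronectin, had a log2 difference of 3.32, at 5293 against 529. In all, 296 of 11264 genes past the intensity floor were at least 2-fold higher and 275 at least 2-fold lower.

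Of 22 measured epithelial junction genes, 17 were at least 2-fold lower in ethanol and 0 higher, with a median log2 difference of -1.99, outside the middle 95% of 10000 random lists matched on expression. The desmosomal cadherins DSC3, DSC2 and DSG3 were 14.5, 14.2 and 12.1-fold lower, and the tight junction gene CLDN1 was 11.6-fold lower. Of 19 cornification genes, which build the outer layer of stratified epithelium, 11 were at least 2-fold lower and 0 higher, with a median of -1.42. SPRR1A, a gene of the cornified envelope, was 12.6-fold lower and KRT10 11.4-fold lower. Of 14 basal and myoepithelial genes, 8 were lower and 1 higher by 2-fold, with a median of -1.32. The keratin genes KRT16, KRT15 and KRT14 of that list were 9.63, at least 4.48 and 5.79-fold lower, and MME, which encodes the peptidase neprilysin, was 3.61-fold higher. Luminal epithelial genes went both ways, with 5 of 14 at least 2-fold lower and 1 higher. CD24 and EPCAM were at least 8.27 and 7.19-fold lower, whereas the simple keratin KRT8 was 2.08-fold higher and its partner KRT18 had a log2 difference of 0.03.

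Of 22 measured mesenchymal transition genes, 10 were at least 2-fold higher in ethanol and 0 lower, with a median log2 difference of 0.83. Besides FN1, the transcription factor genes TWIST1, ZEB2 and ZEB1, which repress epithelial genes, were 6.69, at least 4.52 and 3.03-fold higher. The intermediate filament gene VIM had a log2 difference of 0.87. Of 18 TGF-beta and BMP genes, 7 were higher and 0 lower by 2-fold, with a median of 0.62. The ligand TGFB2 was 19.4-fold higher, and the matricellular genes CCN2 and CCN1 were 10.02 and 3.67-fold higher. Of 14 matrix protease and inhibitor genes, 4 were higher and 1 lower, among them the protease inhibitor SERPINE2, at least 20.1-fold higher, and the gelatinase MMP2 at 6.78-fold higher. Adipocyte markers were also higher, with 3 of 5 past 2-fold and a median of 1.15. FABP4, a fatty acid carrier, was at least 30.8-fold higher, at 2163 against 41.8 in the control, which is under the floor, and the nuclear receptor gene PPARG was 2.68-fold higher. Among the collagen genes that mark fibroblasts, COL1A1, COL1A2 and COL3A1 had log2 differences of 0.11, 0.00 and 0.02. With the mean of a gene's probes in place of the brightest, FN1 and ZEB2 had log2 differences of 1.99 and 1.24. With no floor the list medians were under 1.5-fold for TGF-beta and BMP genes, at 0.48, and for adipocyte markers, at 0.28.

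Outside these lists, genes far above control in ethanol included TFPI2, a protease inhibitor gene, at least 23.5-fold higher, the protocadherin gene PCDH18, at least 9.94-fold higher, and the fatty acid transporter CD36, 21.1-fold higher. CALB1, which encodes a calcium-binding protein, was 31.3-fold lower at 109 against 3407. The uroplakin gene UPK1B was at least 16.6-fold lower and the serpin gene SERPINB3 at least 9.64-fold lower. Inflammatory genes were divided, with 4 of 27 higher and 6 lower by 2-fold. The chemokine genes CCL20 and CXCL8 were 3.41 and at least 3.18-fold higher, and S100A7, IL1A and IL1B were at least 5.33, 5.71 and at least 3.34-fold lower. Of 23 genes of the unfolded protein and integrated stress responses, 5 were lower and 0 higher, including CHAC1 at 3.12-fold and TRIB3 at 2.80-fold lower. Of 21 listed genes of alcohol and aldehyde metabolism, 10 were past the floor, and none of these reached 2-fold in ethanol or in acetaldehyde. The same held for 11 metallothioneins, 11 heat shock genes, 6 stemness genes, 15 ribosomal protein genes and 20 genes of oxidative phosphorylation. Among the alcohol and aldehyde genes, ALDH2, ALDH3A1, ALDH3A2 and ALDH9A1 had equal values in all 3 arrays. Of 34 proliferation genes, 1 reached 2-fold in ethanol, TYMS, the thymidylate synthase gene, 2.04-fold higher.

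The second comparison asked the same of acetaldehyde. Fewer genes differed than in ethanol, and junction genes stood close to control. HAS2, which encodes a hyaluronan synthase, was at least 9.95-fold higher, and FN1 was 7.94-fold higher at 4204. CDH1 had an intensity of 1262, a log2 difference of 0.18. In all, 115 of 11194 genes were at least 2-fold higher and 6 at least 2-fold lower. At 1.5-fold the counts were 242 higher and 46 lower.

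Of 22 mesenchymal transition genes, 7 were at least 2-fold higher in acetaldehyde and 0 lower, with a median log2 difference of 0.44. They included TWIST1, LOX and SPARC, 4.45, 4.05 and at least 2.31-fold higher. LOX encodes a collagen cross-linking enzyme and SPARC a matrix protein. Of 18 TGF-beta and BMP genes, 3 were past 2-fold, TGFB2, CCN2 and CCN1, at 7.15, 4.62 and 2.83-fold higher. None of 22 junction genes reached 2-fold, and their median was -0.15. Of 19 cornification genes, 3 were lower by 2-fold, with a median of -0.26. These were KRT10, SPRR1A and KRT1, 4.00, 2.50 and 2.08-fold lower. The other 3 genes past 2-fold downward were the bile acid transporter family member SLC10A5, the growth factor gene HBEGF and the actin-binding gene POF1B, at least 2.21, 2.14 and 2.12-fold lower. Medians of 17 of 30 lists lay outside the middle 95% of random lists, but none of the 30 had a median of 1.5-fold or more. With so many equal values that range was narrow, -0.0004 to 0 for the mesenchymal list, so small medians could lie outside it. With the mean of its probes FN1 had a log2 difference of 1.60 in acetaldehyde.

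Acetaldehyde and ethanol were then compared directly, at doses that differ in the labels. In acetaldehyde 208 of 11221 genes were at least 2-fold higher than in ethanol and 59 at least 2-fold lower. Of 22 junction genes 16 were higher in acetaldehyde and 0 lower, with a median log2 difference of 1.86. DSC2, DSC3 and CDH1 were 12.9, 12.5 and 10.8-fold higher in acetaldehyde. Of 19 cornification genes 10 were higher, with a median of 1.12, and of 14 basal genes 7 were higher, with a median of 0.99. UPK1B, CALB1 and CD24 were at least 17.6, 27.5 and at least 10.9-fold higher in acetaldehyde. In the other direction, FABP4 and CD36 were 14.3 and 5.43-fold lower in acetaldehyde than in ethanol, the kinase gene LRRK2 was at least 3.30-fold lower and the chemokine gene CCL20 at least 3.60-fold lower. None of the 22 mesenchymal transition genes differed by 2-fold between the compounds, and their median was -0.33. The cornification median was under 1.5-fold with no floor, at 0.49, and with dim values raised to the floor, at 0.47.

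**Figure D1:**
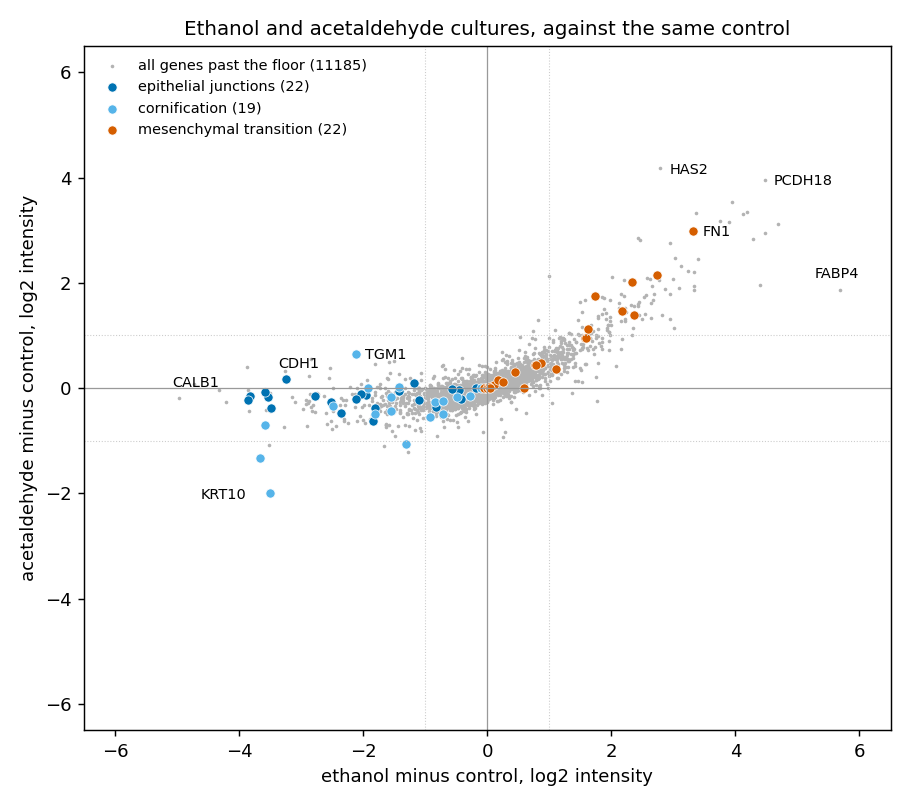
Log2 intensity differences from the shared control for 11185 genes, ethanol on the horizontal axis and acetaldehyde on the vertical axis, with 1 point per gene and 3 gene lists in colour. Mesenchymal genes such as FN1 (3.32 and 2.99) lie to the upper right, whereas junction genes such as CDH1 (-3.25 and 0.18) lie far to the left at about 0 on the vertical axis.

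The 2 control comparisons of that table were correlated across 11185 genes, which are not independent replicates, with r = 0.76 and rho = 0.72. Unchanged arrays simulated against 1 shared control gave a correlation of 0.50, at most 0.52 in 100 simulations. Equal noise in all simulated arrays sets that value in advance, so it is not an estimate from these data. The covariance was 0.0929, against 0.0614 simulated, a difference of 0.0315. The simulated noise came from the difference of the treated arrays, which includes any real difference between the compounds. It therefore does not measure noise between unchanged arrays. Ethanol and acetaldehyde also had equal values in 46.5% of probes, whose differences from control are then identical. The simulated arrays held no such ties, so part of the correlation, above all by rank, may come from them. The lists of genes at least 2-fold higher shared 111 of 272 and 114 genes, where independent lists would share 2.77. The lists of lower genes shared 6 of 275 and 6, where independent lists would share 0.148. The control is a single array and cannot be split, so part of the excess may come from the shared control. Over the 272 genes at least 2-fold higher in ethanol, the median log2 difference in acetaldehyde was 0.86, and over the 275 lower genes it was -0.26.

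The next comparison set the soft agar clone against its own control, to describe cells that had grown without anchorage after ethanol exposure. The clone had lower levels of most junction genes and higher levels of mesenchymal and cell cycle genes. MAL2, a gene of apical transport in epithelial cells, was at least 79.1-fold lower, at an intensity of 7279 in the control and under the floor in the clone. CDH1 had an intensity of 920 in the control and also lay under the floor in the clone, and FN1 was 15.8-fold higher. PCDH18 was at least 24.8-fold higher and the cytokine receptor gene IL7R at least 23.7-fold higher. In all, 1803 of 12262 genes were at least 2-fold higher and 715 at least 2-fold lower, so that 71.6% of these genes were higher. The median over all probes was -0.17, and with differences centred on it 2261 were higher and 544 lower, or 80.6% higher.

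Of 22 junction genes, 19 were at least 2-fold lower in the clone, with a median log2 difference of -2.46. The desmosomal genes DSC3, DSG3 and DSP were at least 27.3, at least 41.8 and at least 55.2-fold lower, and TJP1, a tight junction scaffold gene, was 2.60-fold higher. Of 17 cornification genes 11 were lower and 0 higher, with a median of -1.19, among them KRT10, at least 67.2-fold lower. Of 15 basal genes 9 were lower and 3 higher, with a median of -1.64. KRT16 and CDH3, the P-cadherin gene, were 51.3 and at least 30.1-fold lower, and MME was 5.72-fold higher. Of 24 mesenchymal transition genes 14 were higher and 0 lower, with a median of 1.19. The fibrillin gene FBN1 was at least 5.28-fold higher and SPARC at least 3.58-fold higher. Of 18 TGF-beta and BMP genes 7 were higher and 5 lower, with a median of 0.75. TGFB2 and THBS1, a thrombospondin gene, were at least 14.4 and 26.9-fold higher, while ID2 and TGFB1 were at least 4.53 and 3.50-fold lower. Fibroblast markers were higher as well, 5 of 7 past 2-fold with a median of 1.88, including COL3A1 at 4.19-fold and COL1A1 at 2.21-fold, whereas COL1A2 had a log2 difference of -0.20. The fibroblast median was 0.83 with no floor and 1.15 with dim values raised to the floor.

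Proliferation genes were higher in the clone, 16 of 35 past 2-fold and 0 lower, with a median log2 difference of 0.89. TYMS, the cell cycle marker MKI67 and the replication gene MCM3 were at least 7.78, at least 4.30 and 4.69-fold higher. Of 15 Fanconi and homologous recombination genes 8 were higher and 1 lower, with a median of 1.06. FANCI was 3.93-fold higher and XRCC2 at least 2.15-fold higher. Of 18 immediate early genes 7 were lower and 2 higher, with a median of -0.86. ATF3, JUN and FOS were at least 4.66, 8.11 and 4.42-fold lower, and DUSP6, a phosphatase gene induced by ERK signalling, was at least 2.76-fold higher. Of 21 cholesterol and fatty acid synthesis genes 6 were lower and 3 higher, with a median of -0.66. The sterol genes MSMO1 and HMGCS1 were 5.51 and 4.65-fold lower, whereas the desaturase genes FADS2 and FADS1 were 5.29 and 5.20-fold higher. Among 5 targets of the aryl hydrocarbon receptor 2 were lower and 0 higher, with a median of -0.82. CYP1A1 and TIPARP were at least 18.2 and 3.31-fold lower, whereas CYP1B1 had a log2 difference of 0.10. NFE2L2 and ALDH3A1 had -0.82 and -0.71. Of 10 alcohol and aldehyde genes, ALDH1B1 and ADH5 were 4.93 and 2.56-fold higher and ALDH3B2 at least 4.12-fold lower. Of 9 metallothioneins, MT1X was 2.17-fold lower, and no other reached 2-fold. With no floor the medians of the Fanconi and TGF-beta lists were under 1.5-fold, at 0.57 and 0.24, as was the Fanconi median with dim values raised to the floor, at 0.40. With centring the cholesterol and fatty acid median was -0.50, which no longer reached 1.5-fold.

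**Figure D2:**
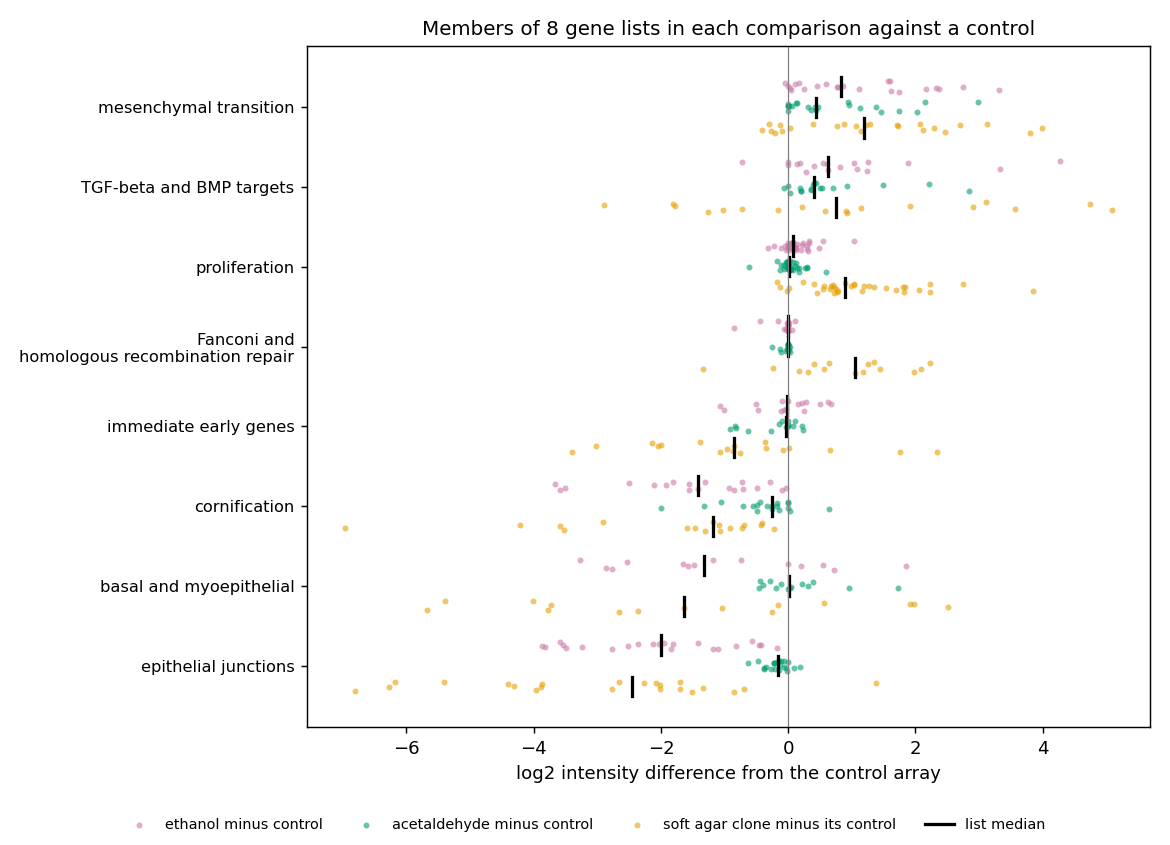
Log2 intensity differences from the control array for the measured members of 8 gene lists, with 1 point per gene, a colour per comparison and a black bar at each list's median. The junction medians were -1.99 in ethanol, -0.15 in acetaldehyde and -2.46 in the clone, and the proliferation median was 0.89 in the clone.

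The clone and ethanol comparisons share no array, and their differences were correlated across 10503 genes with r = 0.59 and rho = 0.37. Of 279 genes at least 2-fold higher in ethanol, 229 (82.1%) were also at least 2-fold higher in the clone, where independent lists would share 44.4. Of 245 lower genes, 196 (80.0%) were also lower in the clone, where independent lists would share 15.1. The clone differs from its control by ethanol exposure and, unless that control was also selected, by growth in soft agar. These cannot be told apart here, so the overlap is not a repeat of the ethanol comparison. The acetaldehyde and clone comparisons gave r = 0.40 and rho = 0.23 across 10451 genes. They shared 103 of the 109 genes higher in acetaldehyde, against 17.1 for independent lists, and 5 of its 5 lower genes, against 0.310, or 3 of 5 with dim values raised to the floor.

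Across all 3 comparisons with a control, 100 of 10445 genes were at least 2-fold higher each time, against 0.424 for independent lists, and they made up 92.6% of the genes higher in acetaldehyde. PCDH18 was at least 9.94-fold higher in ethanol, at least 6.98-fold in acetaldehyde and at least 24.8-fold in the clone. The proteoglycan gene SRGN was 17.3, 9.89 and at least 16.6-fold higher, in the same order. ANGPT1, which encodes the secreted ligand angiopoietin, was 14.9, 8.97 and at least 20.4-fold higher. DKK1, a secreted Wnt antagonist gene, was 6.68, 4.35 and 18.5-fold higher. By the deposited values 5 genes were at least 2-fold lower each time, KRT10, SPRR1A, KRT1, POF1B and HBEGF, where independent lists would share 0.00728. KRT1 and POF1B lay under the floor in the clone, where taken against the floor they were at least 1.19 and at least 1.24-fold lower. With dim values raised to the floor, 79 genes were higher each time and 3 lower, KRT10, SPRR1A and HBEGF. Part of the overlap of ethanol with acetaldehyde may come from their shared control array.

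**Figure D3:**
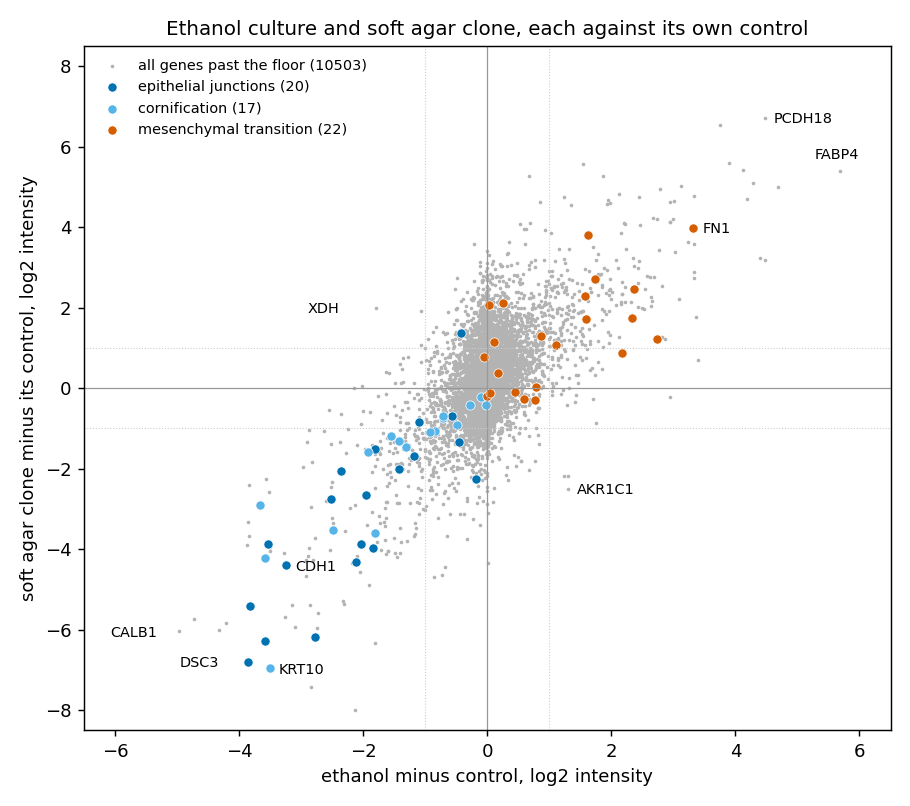
Log2 intensity differences for 10503 genes, ethanol minus its control on the horizontal axis and the soft agar clone minus its own control on the vertical axis, with 1 point per gene and 3 gene lists in colour. Junction and cornification genes lie mostly to the lower left, CDH1 at -3.25 and -4.40, and mesenchymal genes mostly to the upper right, FN1 at 3.32 and 3.99.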

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

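All tests in this part were chosen after the results were seen. In ethanol and in the clone 6 genes differed at least 2-fold in opposite directions, each against its own control, and these differences were not tested. AKR1C1 had log2 differences of 1.30 in ethanol and -2.50 in the clone. AKR1C2 had 1.24 and -2.19, and it is a near-identical paralog of AKR1C1, so the pair may share signal. With the mean of its probes AKR1C1 had 0.65 and -1.58. INSIG1, a regulator of sterol synthesis, had 1.30 and -2.17. ALDH1L2, a mitochondrial folate enzyme gene, had -1.07 and 1.07. SAMD9 had -1.07 and 1.92. XDH, the xanthine dehydrogenase gene, had -1.80 and 1.99.

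The acetaldehyde array held the genes higher in ethanol further from control than the genes lower in ethanol. If its RNA were a mixture of control-like and ethanol-like RNA, the share (acetaldehyde minus control over ethanol minus control, in intensity) would have one median for both sets. Below an intensity of 200, a limit picked after the data were seen, it did, 31.6% in 62 higher genes and 32.6% in 69 lower genes, a difference of -1.08 percentage points. At 200 or more it was 42.1% in 234 and 20.7% in 206 genes, 21.4 points apart, with bootstrap intervals that do not overlap. Those intervals resample genes of single arrays, which are not independent replicates, so they do not measure spread between arrays or cultures. The gap argues against a mixture on a linear scale for these arrays alone. Compression of bright signals predicts that the share moves with brightness in opposite ways, and rho was 0.18 in higher and -0.12 in lower genes. In the dimmest range from 200 up the shares already were 40.9% and 22.2%. Acetaldehyde lay between control and ethanol in 284 of 296 higher and 242 of 275 lower genes. Their selection by the ethanol difference from the same control favours values within that range, so the counts do not test a mixture. A mixture, compressed or not, places no gene outside that range. HAS2 lay outside, at 699 against 38.6 in control and 266 in ethanol. With 1 array per group, such genes cannot be set against noise. A mixture with compression stays open for the genes inside that range, beside a partial shift within the same cells, which was not tested.

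The ethanol and clone arrays had higher mesenchymal and lower junction genes. RNA of fibroblasts in place of epithelial RNA would lower all epithelial genes alike. The lowest log2 difference among KRT7, KRT8, KRT18 and KRT19 was -0.052 in ethanol and -0.51 in the clone. The junction medians were -1.99 and -2.46. The clone's -0.51 is that of KRT19, which was dim, at 190 in its control. The brighter KRT7, KRT8 and KRT18 were no lower than 0.058 there. These values argue against fibroblast RNA as the cause of the lower junction genes, although other epithelial genes such as CD24 were lower too. For the higher mesenchymal genes, COL1A1, COL1A2 and COL3A1 had a median of 0.023 in ethanol and at most 0.11, which argues against it there, although DCN, the only 1 of 4 fibroblast markers past 2-fold, was higher by 1.49, at 88.1 against 31.4, which is under the floor. In the clone that median was 1.15, with COL3A1 at 2.07 and COL1A2 at -0.20, so fibroblast RNA stays open for its mesenchymal genes, and a shift of the epithelial cells themselves, which was not tested, stays open on both arrays. These tests replaced a rank of the collagens among all probes, whose bound had been moved after its values were seen, since levels of different probes cannot be compared.

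Many probes had equal values between pairs of arrays in the 3-array table, 43.9% to 48.2%, against 1.02% in the 2-array table. Median polish of simulated unchanged probe sets gave equal values in 83.5% of pairs over 3 arrays and 0% over 2, which is consistent with summarisation as the source. Small differences in the 3-array table may thus be set to exactly 0. Counts of genes at 1.5-fold or less, the ranges of random lists and the correlation of ethanol with acetaldehyde in that table carry this limit.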

How the results depend on the processing

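No setting turned the direction of the 21 called list medians, or of 543 values of named genes, which were run under lowess, centring and probe means alone. Counts of higher and lower genes moved most with the fold: at 1.5-fold they were 597 and 576 in ethanol, 242 and 46 in acetaldehyde, 3144 and 1867 in the clone and 424 and 249 for acetaldehyde against ethanol. At 3-fold they were 135 and 130, 56 and 1, 757 and 309, and 97 and 12. All other settings kept these counts within 1.5 times. By rank, the correlations were 0.72 for ethanol with acetaldehyde, 0.37 for ethanol with the clone and 0.23 for acetaldehyde with the clone. Ethanol with the clone gave r = 0.54 with no floor and 0.64 with a floor at the 70th percentile. The cause was not tested. With no floor, 1 list was higher in ethanol, 3 in the clone and 0 lists lower in acetaldehyde against ethanol, since dim list members then enter the medians. Without the size requirement, an alternative added after the data were seen, 10 lists were higher and 6 lower in ethanol, 11 and 6 in acetaldehyde, 5 and 10 in the clone and 6 and 9 in acetaldehyde against ethanol. Of 21 called list medians, 21 moved by less than the spread assumed for unchanged genes under lowess and probe means. With no floor 5 moved. Probe means can change only genes with several probes, 895 of 17958 and 769 of 18417, and left most of these medians identical. In the 3-array table median differences were 0 at all levels of brightness, so lowess had almost nothing to correct. Unmatched lists leave the medians as they are. Centring shifts all genes of a comparison alike, by 0 in the 3-array table. Lowess in that table, probe means, unmatched lists and centring could therefore not show that the medians are stable. In the clone lowess could move them, and the Fanconi median was 1.24 against 1.06. The calls themselves held for 20 of 21 with centring and 15 with no floor. With dim values raised to the floor, also added later, 19 of 21 held, the counts were 261 and 238 in ethanol, 96 and 6 in acetaldehyde, 1472 and 611 in the clone and 181 and 49 for acetaldehyde against ethanol, and the clone's correlations were 0.55 with ethanol and 0.37 with acetaldehyde. Of the gene values, 11 moved with probe means, among them FN1 in ethanol at 1.99, ZEB2 in ethanol at 1.24 and IL6 in ethanol at 0.59. With 1 array per group, leaving out arrays, other splits and a paired fit were not possible. Signal close to the floor limits what could be counted for dim genes.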

Other observations

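The receptor gene IL1R1 was at least 6.19-fold higher in ethanol, at least 4.23-fold in acetaldehyde and at least 8.74-fold in the clone, and the decoy receptor gene IL1R2 was 10.3-fold higher in ethanol. Integrin and adhesion genes were divided, with 3 of 16 higher and 5 lower in ethanol. ITGA5, the fibronectin receptor subunit, was 3.46-fold higher, and ITGA2 and ALCAM were 3.38 and 3.33-fold lower. Of 19 interferon response genes 3 were higher and 1 lower, with IFI44L at least 4.34-fold higher in ethanol and at least 5.30-fold higher in the clone, where 7 of 20 were higher and 2 lower. Of 16 immediate early genes 0 reached 2-fold in acetaldehyde, and their median log2 difference was -0.03. DUSP6, SPRY4 and SPRY2 had -0.92, -0.84 and 0.08 in acetaldehyde and 0.25, 0.28 and 0.62 in ethanol.

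In the clone, Notch and Wnt genes went both ways. Of 20 Notch pathway genes 5 were at least 2-fold lower and 3 higher. The targets HES1 and NRARP were 8.68 and 4.35-fold lower and the ligand JAG1 3.75-fold lower, while MAML2, a coactivator gene, was 4.76-fold higher. Of 23 Wnt pathway genes 4 were lower and 2 higher. The ligand WNT5A was at least 11.3-fold higher and the antagonist DKK1 18.5-fold higher, and SFRP1, another antagonist, was at least 3.44-fold lower. Of 24 NRF2 and oxidative stress genes 7 were lower and 1 higher, with AKR1B10 at least 32.7-fold and GPX2 at least 15.01-fold lower. Of 23 hypoxia and glycolysis genes 7 were higher and 2 lower, among them BNIP3 at 4.72-fold higher and ADM at 9.58-fold lower. The protease gene MMP7 was at least 4.74-fold higher.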
